A study of Homo sapiens with 6 samples.

How the data were processed

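RNA sequencing was done on MCF-7 cells, an established estrogen receptor-positive human breast cancer line, after exposure to EPZ5676 or to DMSO, the solvent control. Per the labels, each condition had 3 libraries, prepared from poly(A)-selected RNA with random hexamer priming. The dose of EPZ5676 and the time of exposure are not given in the sources used here. The labels name no batch. They do not say that the 3 libraries of a condition came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

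The authors deposited 1 table of read counts with a column for each of the 6 libraries and 20382 rows, each a transcript identifier paired with a gene name. Per the submitters' processing notes, the tools were STAR 2.7.10a and featureCounts 2.0.1, and the genome build was hg38. The strand setting, the annotation release and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies or overlapping neighbours are therefore uncertain, among them HLA-A, HLA-B, HLA-C, KRT81 with KRT86, and IFNL2 with IFNL3. The deposited values were whole numbers that summed to between 15739098 and 17551767 per library, and they were used as raw counts. Of the rows, 3382 had a count of 0 in every library, 15 carried a gene name shared with another row, and 595 had an Ensembl identifier in place of a symbol. Mitochondrially encoded transcripts were not analysed here, since 0 of the 15 listed names matched a row.

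Differential expression was tested with the quasi-likelihood test of edgeR 4.0.16 (robust, 2-sided) under R 4.3.3, after TMM scaling and the filterByExpr filter with a minimum count of 10 and a minimum total of 15. The filter left 13185 genes. Treatment was the only term in the model, and p-values were adjusted with the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Levels are TMM-scaled CPM, read counts divided by the scaled library total and multiplied by 1e6, given as the mean ± SD of 3 libraries. Fold changes are given as log2 values, EPZ5676 over DMSO, with the standard error (SE) as the absolute log2 fold change divided by the root of the F statistic. A gene was described as having risen or fallen only where its adjusted p was under 0.05. A count of 3 was worth 0.171 to 0.191 CPM in these libraries, and intervals on counts cover counting error only.

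Before the data were examined, 41 gene lists were fixed. They covered the interferon response, MHC class I presentation, estrogen-induced and estrogen-repressed genes, TGF-beta targets, chromatin complexes around DOT1L, menin and Polycomb, HOX and MEIS genes, cell cycle, stress, metabolic and signalling groups, cytosolic ribosomal proteins, and markers of luminal, basal, mesenchymal, immune, endothelial and neuronal cells. The 39 lists with at least 5 tested members were compared with all other tested genes by camera (limma 3.58.1, preset correlation of 0.01 between genes, log2 CPM with a prior count of 2), adjusted over the 39 lists. The named genes follow a rule that was also fixed then. It takes DOT1L, MEN1 and KMT2A whatever their values. It adds the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold with a group mean of at least 5 CPM and no overlap between the groups, and the 5 with the smallest adjusted p in each direction. From each list it takes up to 4 members with the smallest adjusted p, and members named to show what a list did. Other genes were named after their values were seen, as stated where they appear.

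Gene coordinates, GC content, transcript length and gene span came from GENCODE release 29 on GRCh38, the same assembly as hg38, matched on the transcript identifier without its version. A match was found for 96.8% of the tested rows. The alternatives tried were 3 other scalings, DESeq2 1.42.0, limma-voom, a looser and a stricter filter, thinning of all libraries to the smallest total, the replicate number as a block, each library left out in turn, an estimated correlation within lists, the fry test and 10 expression classes. Added after seeing the data were a correction for trends on GC content, transcript length and gene span, a direct test of changes over 1.2-fold, and a shortened MHC list. That correction is called the GC and length correction below. The procedure was tested on simulated counts for the EPZ5676 and DMSO comparison, drawn from the means, dispersions and library sizes of these libraries over 13089 tested genes. Of 50 genes altered at each fold, 40% were recovered at 1.2-fold, 74.0% at 1.5-fold, 92.0% at 2-fold and 98.0% at 4-fold. Unaltered genes made up 3.31% of the 181 calls, and 0 of 39 unaltered lists passed the list test. The simulated genes were drawn independently of each other and without a GC trend, and far fewer were altered than changed in the data. The simulation therefore cannot show false calls that come from correlated genes or from a GC trend.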

Results

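Transcript levels were measured by RNA sequencing in MCF-7 cells treated with EPZ5676, an inhibitor of DOT1L, the enzyme that methylates lysine 79 of histone H3. The control cells received DMSO. The study's title names menin as a protein that recognises this methylation, and the comparison asks which transcripts differ when DOT1L is inhibited. Each group had 3 libraries. The totals were 17551767, 16230980 and 16112915 counts in DMSO and 15739098, 16060239 and 16647793 in EPZ5676. Of the 20382 rows in the table, 15241 to 15337 were above 0 in a DMSO library and 15519 to 15563 in an EPZ5676 library. The first principal component held 62.6% of the variance and separated the groups.

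In EPZ5676-treated cells, 34 of 36 tested genes of the interferon response rose and none fell. The other main pattern was weaker, since 33 of 48 tested estrogen-induced genes fell and 4 rose. Its list test did not pass with an estimated correlation between genes (adjusted p = 0.0972), a setting in which only 1 list passed. IFIT1, which binds foreign RNA, rose 28.5-fold, from 2.29 ± 0.365 to 65.8 ± 5.92 CPM (mean ± SD, n = 3 libraries per group). IFI6, another interferon-stimulated gene, rose 9.61-fold, from 25.1 ± 3.22 to 241 ± 16 CPM. ESR1, the gene of estrogen receptor alpha, was 2.04-fold lower, at 343 ± 4.01 CPM in DMSO and 168 ± 7.82 CPM in EPZ5676. GREB1, a target of that receptor, was 2.40-fold lower, and IGF1R, the receptor for insulin-like growth factor 1, was 2.33-fold lower.

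In total 4131 of 13185 tested genes changed, of which 2041 rose and 2090 fell (edgeR quasi-likelihood test, adjusted p under 0.05). At an unadjusted p under 0.05 the count was 5427. Most of the changes were small, and 68.8% of the changed genes had an absolute log2 fold change under 0.5. Changes of at least 1 on the log2 scale were 456 rises and 48 falls. The 3 values of one group did not overlap the 3 of the other in 42.2% of tested genes, where chance gives 10%. Without DMSO replicate 2, 1344 genes rose.

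**Figure D1:**
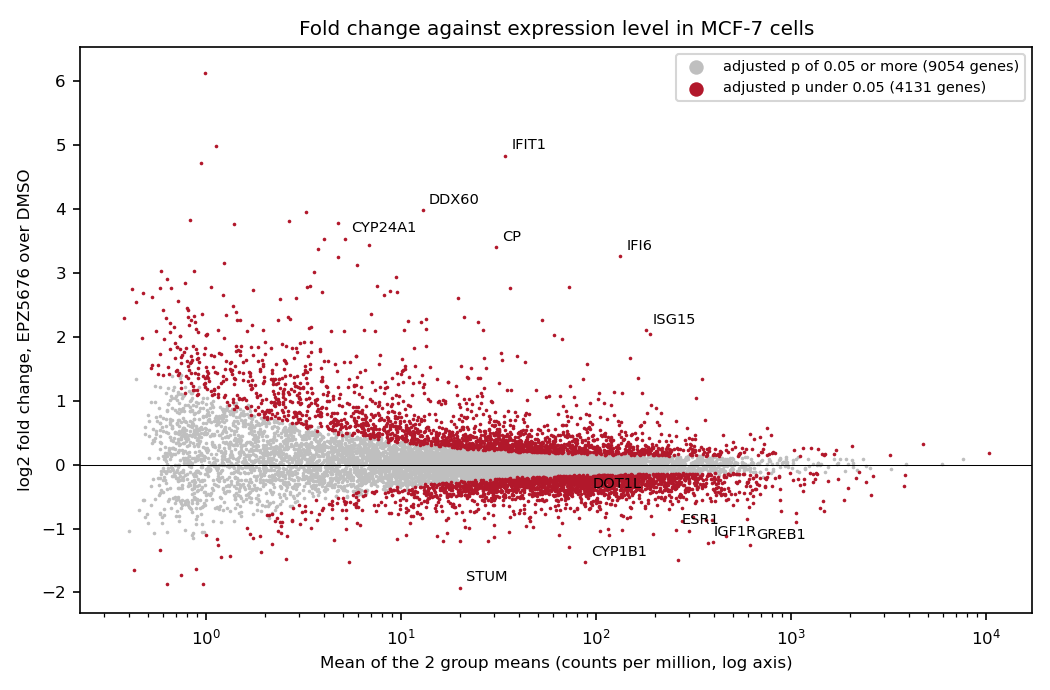
Each point is 1 of 13185 tested genes, with the mean of both group means in CPM on a log x axis and the log2 fold change of EPZ5676 over DMSO on the y axis. The 4131 coloured points passed an adjusted p of 0.05, and IFIT1 at 4.83 and STUM at −1.92 are among the labelled genes.

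The 12 largest rises under the naming rule held 8 interferon-stimulated genes. IFIT1 (ENST00000371804.4, chromosome 10, 89392546 to 89406486, GRCh38) had a log2 fold change of 4.83 (SE 0.12, adjusted p = 6.63e-19). DDX60 followed at 3.98, MX2 at 3.95, IFIT3 at 3.78, CMPK2 at 3.53, IFI27 at 3.44, IFI6 at 3.26 and OAS2 at 3.25. The other 4 were CYP24A1, which inactivates vitamin D, at 3.54 (SE 0.23), CP, the copper-binding ceruloplasmin, at 3.40 (SE 0.12), CDH5, the cadherin of endothelial junctions, at 3.38 (SE 0.26), and PZP, a protease inhibitor, at 3.12 (SE 0.20). CP went from 5.30 to 56.1 CPM, whereas CYP24A1 and CDH5 stayed under 10 CPM in EPZ5676. IGFBP3, which binds insulin-like growth factors, was among the 5 rises with the smallest adjusted p, at 2.78 (SE 0.08, adjusted p = 4.47e-18).

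The 12 largest falls under the same rule spanned log2 fold changes from −1.92 to −1.18. STUM (chromosome 1, 226548800 to 226609214) was 3.80-fold lower, and CYP1B1, a cytochrome P450 that hydroxylates estradiol, was 2.88-fold lower. TNRC18 went from 389 ± 37.2 to 139 ± 22.4 CPM. ITIH2, SFXN2, GREB1, IGF1R, GFRA1, GPER1, AMZ1, CXCL12 and AGR3 completed the group. GFRA1, a co-receptor for GDNF, had the smallest adjusted p among the falls (3.60e-15), at 552 ± 6.30 CPM in DMSO and 238 ± 3.49 CPM in EPZ5676. IGFBP4 fell by 1.11 on the log2 scale.

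**Figure D2:**
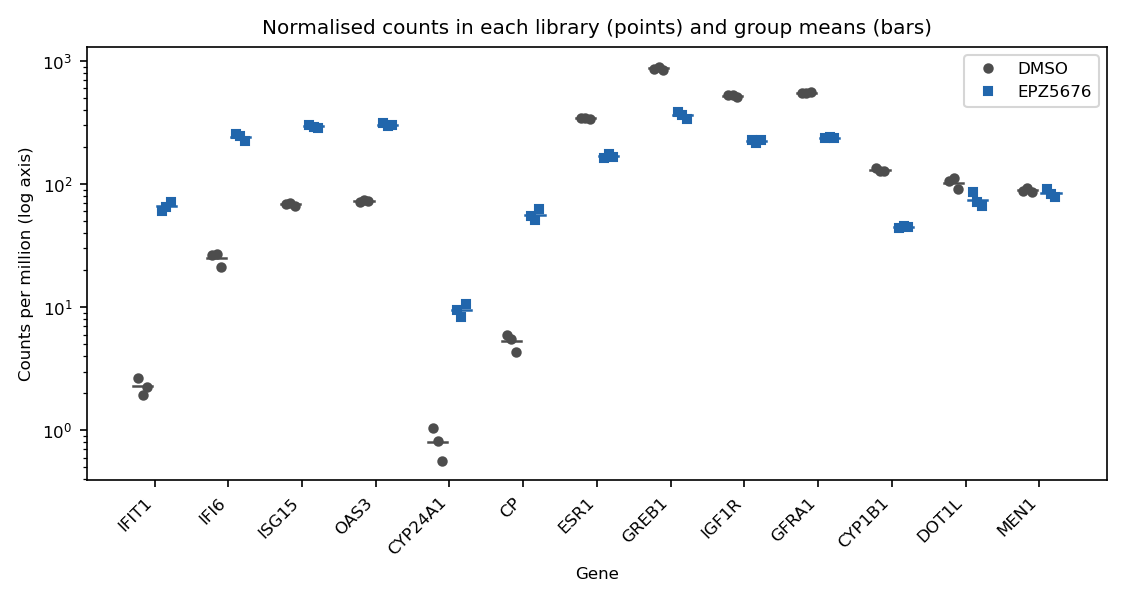
Points are the CPM of each library for 13 named genes on a log y axis, circles for DMSO and squares for EPZ5676, and bars are group means of 3 libraries. The groups do not overlap for the 6 genes from IFIT1 to CP, which were higher in EPZ5676, or for the 6 from ESR1 to DOT1L, which were lower.

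Of 36 tested genes of the interferon response, 34 rose and none fell, with the same counts adjusted over the list alone. The median log2 fold change was 2.12 and the list test gave an adjusted p of 6.27e-30, or an adjusted p of 0.00669 with an estimated correlation. The median did not move when 3 members with at most 3 counts in DMSO were set against a floor of 3 counts. It could hardly have moved, since genes that low in DMSO passed the filter only through their counts in EPZ5676. OAS3, a sensor of double-stranded RNA, rose from 73.0 ± 1.15 to 303 ± 9.45 CPM, and ISG15, a ubiquitin-like modifier, rose from 68.4 to 294 CPM. STAT1, the transcription factor of the pathway, had a log2 fold change of 1.34. IRF1 and ISG20 did not pass, at 0.17 and 0.19. The list as a whole made up 637 to 663 CPM, here scaled by the library total, in the DMSO libraries and 2345 to 2393 in the EPZ5676 libraries.

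Of 14 tested genes of MHC class I presentation, 11 rose and none fell, also when adjusted over the list alone. The peptide transporters TAP1 and TAP2 had log2 fold changes of 1.16 (SE 0.09) and 1.27 (SE 0.13). HLA-B rose by 0.61 and HLA-C by 0.50, whereas HLA-A was at 0.03 with an adjusted p of 0.763. Reads of these HLA genes can be shared among them. The list test gave an adjusted p of 3.56e-05, and an adjusted p of 0.206 with an estimated correlation. TAP1 and 2 immunoproteasome genes, PSMB8 and PSMB9, also belong to the interferon list.

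Of 48 tested estrogen-induced genes, 33 fell and 4 rose (33 and 5 adjusted over the list alone), with a median log2 fold change of −0.41. GREB1 (chromosome 2, 11482341 to 11642788) had a log2 fold change of −1.26 (SE 0.05, adjusted p = 9.76e-15). STC2 was at −1.03 and CA12, a carbonic anhydrase, at −0.82. PGR, the progesterone receptor gene, was at −1.17, and TFF1, a secreted trefoil peptide, was at −0.48. The 4 that rose were HSPB8, ELOVL2, P2RY2 and OLFM1, the last with an adjusted p of 5.70e-04 to 0.0983 over its 16 alternatives, while MYC stood at 0.02 with an adjusted p of 0.829. The list test gave an adjusted p of 3.36e-09, and an adjusted p of 0.0972 with an estimated correlation.

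Of 25 tested estrogen-repressed genes, 13 rose and 2 fell. BCAS1 rose from 212 ± 1.32 to 437 ± 20.2 CPM. TGFB2, a TGF-beta ligand, rose by 1.35, IL1R1 by 1.29 and PSCA by 0.78 on the log2 scale. The 2 that fell were CDKN1B, a cyclin-dependent kinase inhibitor, and IRS2, an adaptor of insulin signalling. The list test gave an adjusted p of 8.11e-05, and an adjusted p of 0.0999 with an estimated correlation.

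Of 22 tested TGF-beta targets, 12 rose and 2 fell. ITGB6, an integrin subunit, rose from 30.1 ± 1.75 to 67.7 ± 2.26 CPM. CCN2 had a log2 fold change of 1.42 (SE 0.14), and BMP7 had 0.47. SKI and LTBP1 fell, and 4 genes fell without EPZ5676 replicate 1. The list test gave an adjusted p of 0.0177. It gave an adjusted p of 0.0747 without EPZ5676 replicate 1 and an adjusted p of 0.221 with an estimated correlation, and over the 17 alternatives the range was 4.27e-04 to 0.221.

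Of 74 tested cytosolic ribosomal protein genes, 22 rose and 1, RPS2, fell (21 and 1 adjusted over the list alone), with a median log2 fold change of 0.07. The count of rises depended on the setting, with 35 under library totals, 11 and 8 without DMSO replicates 1 and 2 and 8 without EPZ5676 replicate 2, and 5 genes fell without EPZ5676 replicate 1. RPS15A and RPL21 both rose by 0.35, and the call of RPS2, at −0.22, ended under the GC and length correction (−0.10, adjusted p = 0.0587, with a range of 1.58e-06 to 0.0587 over its 16 alternatives). The list test gave an adjusted p of 0.0437, and an adjusted p of 0.657 with an estimated correlation. It was above 0.05 when any library but EPZ5676 replicate 3 was left out, with adjusted p of 0.0641, 0.221 and 0.0666 without DMSO replicates 1, 2 and 3 and 0.0585 and 0.0925 without EPZ5676 replicates 1 and 2. It was also above 0.05 under 5 other settings, and over the 17 alternatives the range was 0.00869 to 0.657.

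**Figure D3:**
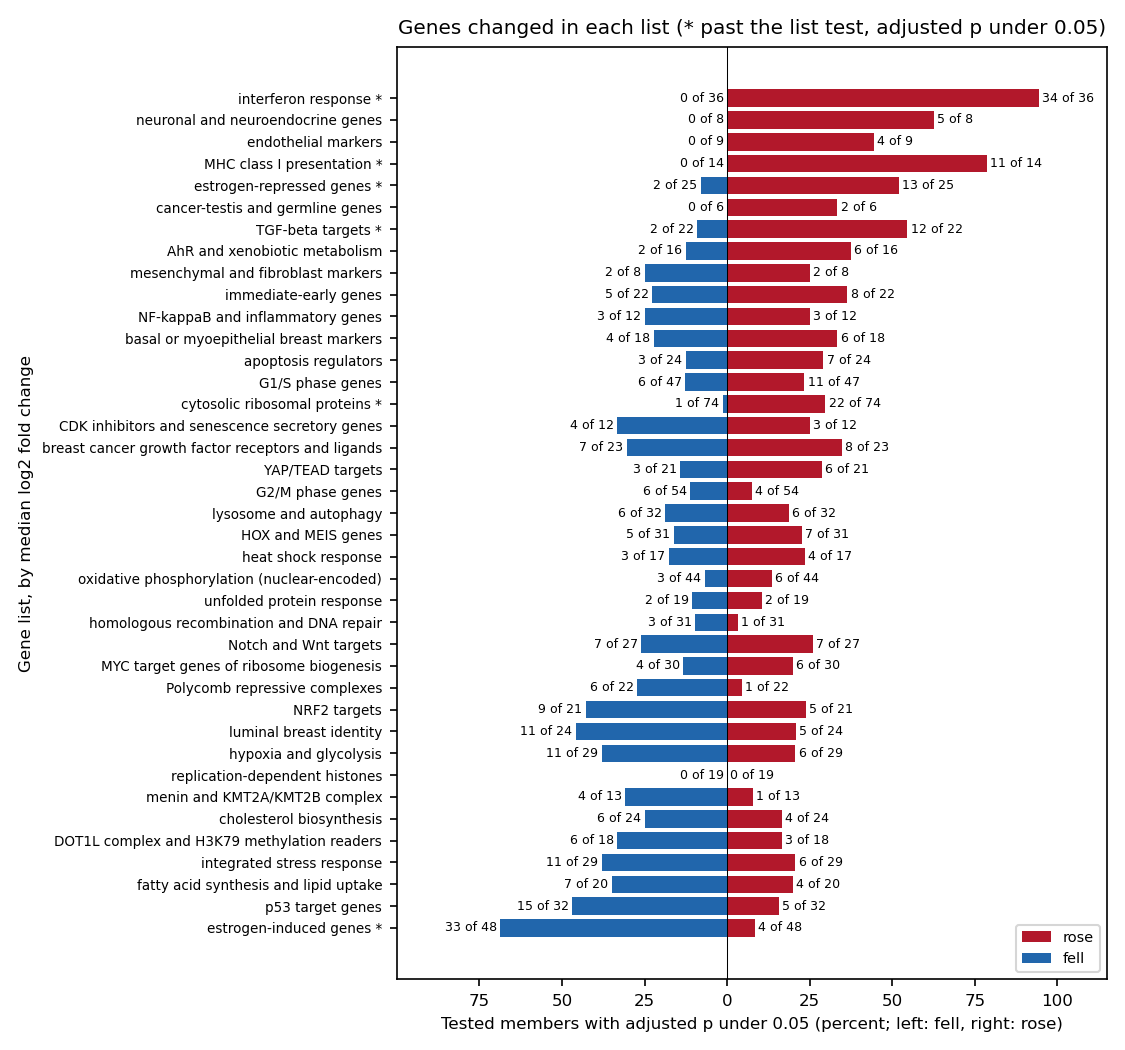
Bars give the percent of tested members of each list with an adjusted p under 0.05, risen to the right and fallen to the left, with the counts printed at the bar ends and lists ordered by median log2 fold change. Asterisks mark the 6 lists past the list test, among them the interferon response with 34 of 36 members risen and the estrogen-induced genes with 33 of 48 fallen.

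DOT1L itself, the target of the inhibitor (chromosome 19, 2164149 to 2232578), fell from 103 ± 10.6 to 74.4 ± 10.1 CPM (log2 fold change −0.47, SE 0.08, adjusted p = 1.43e-04). MEN1, which encodes menin (chromosome 11, 64803510 to 64811294), was at 89.4 ± 3.25 CPM in DMSO and 84.4 ± 5.95 CPM in EPZ5676, a difference that did not pass the test (log2 fold change −0.08, SE 0.07, adjusted p = 0.366), and under the GC and length correction its direction turned, at 0.08 (adjusted p = 0.255, with a range of 0.0833 to 0.749 over its 16 alternatives). KMT2A, a histone H3 lysine 4 methyltransferase that binds menin, had a log2 fold change of −0.23 (SE 0.07, adjusted p = 0.00964). The KMT2A call ended without DMSO replicate 2 (adjusted p = 0.0807) and without EPZ5676 replicate 2 (adjusted p = 0.0751), and over the 16 alternatives its adjusted p ranged from 7.28e-05 to 0.0807. Among 18 genes of the DOT1L complex and H3K79 methylation readers, 3 rose and 6 fell (3 and 8 adjusted over the list alone, and only 1 rise without DMSO replicate 1, 2 or 3 or EPZ5676 replicate 2 or 3), with TRRAP at −0.32, MLLT1 at −0.40 and AFF1 at −0.39. Among 13 genes of the menin and KMT2A/KMT2B complex, 1 rose and 4 fell, with HCFC1 at −0.45. Without DMSO replicate 1, 2 or 3 or EPZ5676 replicate 2 or 3, no gene of this complex rose and 2 to 4 fell. Under the GC and length correction KMT2A, TRRAP, MLLT1 and HCFC1 shrank to −0.15, −0.18, −0.25 and −0.26, all still past the threshold. Among 22 Polycomb genes, 1, RNF2, rose and 6 fell, with JARID2 at −0.47. Of 31 HOX and MEIS genes, 7 rose and 5 fell, with HOXB9 at 1.70 and HOXC9 at −0.75. None of these 4 lists passed the list test, with adjusted p of 0.250, 0.164, 0.390 and 0.865.

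Markers of cell types moved in different directions. In the luminal breast list, the line's own identity, 11 of 24 genes fell and 5 rose (list adjusted p = 0.0966). ESR1, XBP1, GATA3 and FOXA1 had log2 fold changes of −1.03, −0.72, −0.41 and −0.39, while the keratins KRT8 and KRT18 were at 0.17 and 0.32. Of 9 endothelial markers, 4 rose and none fell (adjusted p = 0.0966), with CDH5 at 3.38 and ESAM at 0.67. Only 2 of them rose without EPZ5676 replicate 3, and 1 fell without EPZ5676 replicate 1, with no filter or with the replicate number as a block. Of 8 neuronal and neuroendocrine genes, 5 rose and none fell (5 and 1 adjusted over the list alone, adjusted p = 0.0966), with MAP2 at 0.81. Of 18 basal or myoepithelial markers, 6 rose and 4 fell (7 and 4 adjusted over the list alone), and of 8 mesenchymal and fibroblast markers, 2 rose and 2 fell. The 2 falls, COL6A3 and COL3A1, had adjusted p of 0.0398 and 0.0484, with ranges of 0.00582 to 0.218 and 0.0379 to 0.172 over 16 alternatives, and neither was called with library totals, DESeq2, limma-voom or the GC and length correction, or without DMSO replicate 2, DMSO replicate 3 or EPZ5676 replicate 2. Only 4 of 20 immune cell markers passed the filter on counts, of which LCP1 and ITGAM rose. LCP1 went from 6.71 to 10.8 CPM and ITGAM from 0.445 to 1.51 CPM.

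The remaining lists did not pass the list test, and most held changes in both directions. Where a single pair of counts is given, here and for the lists above, those adjusted over the list alone were the same. Of 32 p53 targets, 5 rose and 15 fell (5 and 16 adjusted over the list alone), with RRM2B at −0.44 and TP53INP1 at 0.46. Of 29 genes of the integrated stress response, 6 rose and 11 fell (7 and 13 adjusted over the list alone), with SLC7A11, the cystine transporter, at −0.98. Among 19 genes of the unfolded protein response 2 rose and 2 fell, and among 17 heat shock genes 4 rose and 3 fell. Of 21 NRF2 targets, 5 rose and 9 fell (7 and 9 adjusted over the list alone), and of 29 hypoxia and glycolysis genes, 6 rose and 11 fell, with NDRG1 at 0.78 and PFKP at −0.63. Cholesterol biosynthesis had 4 rises and 6 falls among 24 genes (4 and 8 adjusted over the list alone), and fatty acid synthesis and lipid uptake had 4 rises and 7 falls among 20 (4 and 8 adjusted over the list alone). The fatty acid counts were 2 and 7 without DMSO replicate 1 and 2 and 5 without DMSO replicate 2. FASN, the fatty acid synthase, went from 2211 ± 186 to 1501 ± 224 CPM, a log2 fold change of −0.56 that shrank to −0.31 under the GC and length correction and stayed past the threshold. Among 44 nuclear-encoded genes of oxidative phosphorylation, 6 rose and 3 fell (4 and 2 adjusted over the list alone, but 4 and 5 with no filter and 2 and 3 without EPZ5676 replicate 3), and among 32 lysosome and autophagy genes, 6 rose and 6 fell (7 and 6 adjusted over the list alone).

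Cell cycle genes changed in both directions. Of 47 G1/S genes, 11 rose and 6 fell, with CCNE2 at 0.78 and TYMS at −0.38, and of 54 G2/M genes, 4 rose and 6 fell (2 and 4 adjusted over the list alone). The balance of the G2/M genes turned with 6 rises and 4 falls under upper quartile scaling, 8 and 4 under library totals and 10 and 9 without EPZ5676 replicate 1, while none rose without DMSO replicate 1 or 2, and the G1/S counts were 16 and 3 under library totals, 4 and 4 without DMSO replicate 1 and 4 and 3 without DMSO replicate 2. Replication-dependent histones had no call among 19 genes. That list was fixed as a technical one, and in these poly(A)-selected libraries it is not read as a measure of the cell cycle. MYC targets of ribosome biogenesis had 6 rises and 4 falls among 30 (6 and 5 adjusted over the list alone), and homologous recombination and DNA repair had 1 rise and 3 falls among 31 (1 and 1 adjusted over the list alone). The majority turned in both, to 5 rises and 6 falls with no filter, 2 and 3 without DMSO replicate 2, 7 and 8 without EPZ5676 replicate 1 or with the replicate number as a block, and 3 and 4 without EPZ5676 replicate 2 or 3 for the MYC targets, and to 3 and 2 under library totals for DNA repair. Of 12 cyclin-dependent kinase inhibitors and senescence secretory genes, 3 rose and 4 fell, with SERPINE1 at 2.18 and CDKN1B at −0.43. Among 24 apoptosis regulators, 7 rose and 3 fell (8 and 4 adjusted over the list alone), with BMF at 0.97 and BAX at −0.42. Of 22 immediate-early genes, 8 rose and 5 fell (11 and 5 adjusted over the list alone), of 12 NF-kappaB and inflammatory genes, 3 rose and 3 fell, and of 21 YAP/TEAD targets, 6 rose and 3 fell, with NT5E at 2.29 and MYOF at −0.62. Of 27 Notch and Wnt targets, 7 rose and 7 fell (8 and 9 adjusted over the list alone), with APCDD1 at 1.17 and NOTCH2 at −0.35. Of 16 AhR and xenobiotic metabolism genes, 6 rose and 2 fell, of 23 breast cancer growth factor receptors and ligands, 8 rose and 7 fell, and of 6 cancer-testis and germline genes, 2 rose. The AhR counts were 4 and 1 without EPZ5676 replicate 3, and only 1 fell when any library but DMSO replicate 3 was left out. Only 1 cancer-testis and germline gene rose without DMSO replicate 1 or 3 or EPZ5676 replicate 2 or 3. RET, a receptor kinase, had a log2 fold change of −0.78. The list test gave adjusted p between 0.0966 and 0.955 for these groups.

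Rises were more frequent among weakly expressed genes and falls among strongly expressed ones. When the tested genes were divided into 4 classes of equal size by mean level, 658 genes rose and 98 fell in the lowest class, whose rises included OAS2, MX2 and CYP24A1. The risen share of the changed genes was 87.0%, 57.9%, 41.4% and 30.3% from the lowest to the highest class. In the highest class 441 genes rose and 1015 fell, and GREB1, IGF1R and XBP1 were among the falls. Of the rises of at least 1 on the log2 scale, 372 lay in the lowest class and 14 in the highest, and of such falls, 23 and 13. No test was made, because genes are not replicates.

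Changes also followed the GC content of the transcript. In the fifth of genes with the lowest GC content 568 rose and 130 fell, and in the fifth with the highest 186 rose and 832 fell, with median log2 fold changes of 0.10 and −0.16. The libraries differed in this trend. It was measured on each gene's log2 deviation from its DMSO mean, as the median over the highest GC group minus that over the lowest, the outer groups above. The DMSO values therefore centre near 0 by construction. The trend was 0.07, 0.06 and −0.12 in DMSO and −0.04, −0.29 and −0.42 in EPZ5676. After a correction for GC content and length, chosen after seeing the data, 4211 genes changed, of which 3269 were among the 4131, with 3268 in the same direction and 1 reversed. DOT1L moved from −0.47 to −0.30 and GREB1 from −1.26 to −1.17, both still past the threshold, while the call of JUND, an AP-1 subunit, at −0.42 before the correction, ended at −0.11 (adjusted p = 0.0674, with a range of 2.99e-16 to 0.0674 over its 16 alternatives).

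**Figure D4:**
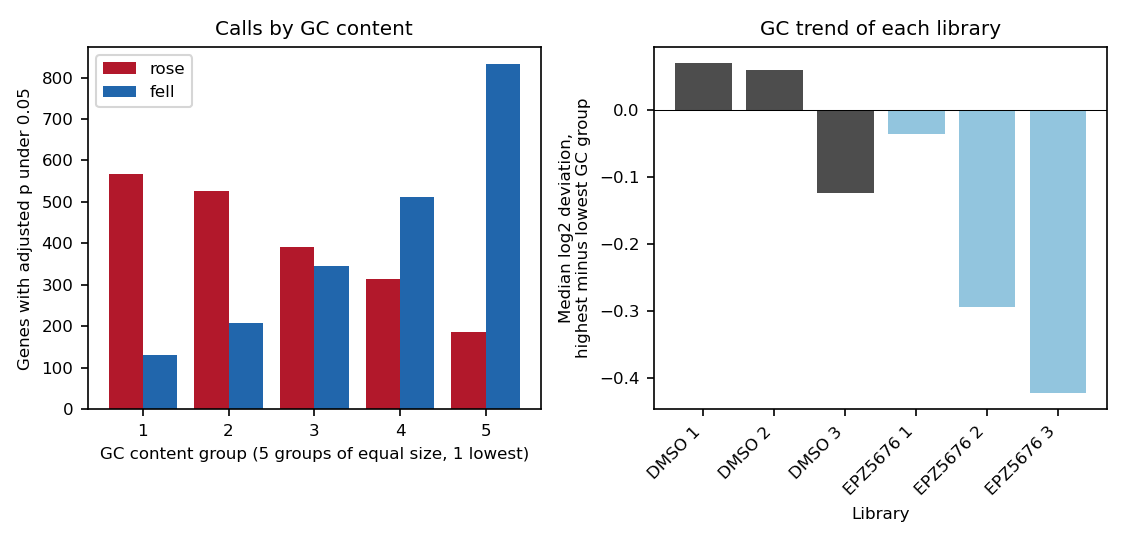
The left panel counts genes with an adjusted p under 0.05 in 5 groups of equal size by transcript GC content, with 568 risen and 130 fallen in the lowest group and 186 and 832 in the highest. The right panel gives for each library the median log2 deviation from the DMSO mean, highest GC group minus lowest. It runs from 0.07 in DMSO replicate 1 to −0.42 in EPZ5676 replicate 3.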

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

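The GC and length correction, the direct test of changes over 1.2-fold, the shortened MHC list and the expression class results under other scalings, tests and libraries were chosen after the results were seen. The count of 4131 changed genes stayed within 1.5 times under 3 scalings, DESeq2, limma-voom, both filters, thinning and the GC and length correction, at 3739 to 4355. With libraries scaled by their totals, 2632 genes rose and 1592 fell, against 2041 and 2090. A direct test of changes over 1.2-fold gave 1211 genes, 771 higher and 440 lower, since it asks for a larger change. Leaving out 1 library gave 2824 to 5063 changed genes, 1344 to 2449 higher and 1480 to 2614 lower. The lowest counts were without DMSO replicate 2. All 3633 to 4079 calls shared with TMM scaling and edgeR under the other scalings, limma-voom and DESeq2 had the same direction. No scaling moved the median of all genes by more than 0.05 on the log2 scale.

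The 6 gene lists past the list test became 1, the interferon response, with an estimated correlation, 22 with fry, which does not compare a list with other genes, and 9 with the GC and length correction, which added p53 targets (adjusted p = 0.0331), endothelial markers (0.0474) and immediate-early genes (0.0172). Their ranges over all alternatives were 9.86e-04 to 0.368, 9.86e-04 to 0.368 and 0.0172 to 0.562. The interferon response passed under all 17 alternatives. The MHC list passed without the 3 shared genes. The estimated correlation was 2.09e-04 in the interferon, −0.0136 in the estrogen-repressed and −0.0187 in the TGF-beta list, under the preset 0.01. In these lists the weaker result under that setting therefore does not come from a higher correlation between members. The estimates were above the preset in the estrogen-induced, MHC and ribosomal lists, at 0.0194, 0.0639 and 0.145. Ribosomal proteins ended above 0.05 under RLE scaling (0.0565), no filter (0.0624), the strict filter (0.0604) and thinning (0.0604), and the cause was not tested. Leaving out 1 library gave 4 to 6 lists. In 29 of 39 lists some alternative moved the count of risen or fallen members by over 1.5 times, and in 4 the majority turned, the G2/M genes, oxidative phosphorylation, MYC targets and DNA repair. The range was 8 to 35 rises for ribosomal proteins, 2 to 7 rises and 7 to 13 falls for the integrated stress response, 3 to 5 and 10 to 16 for p53 targets, and 5 to 11 and 3 to 5 for immediate-early genes.

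Whether the replicate numbers pair the libraries was not settled. The deviations of same-numbered libraries correlated at only 0.08, −0.04 and 0.14, and not every library correlated best with its own number. The GC trend, however, fell from replicate 1 to 3 in both groups, with 0.07, 0.06 and −0.12 in DMSO and −0.04, −0.29 and −0.42 in EPZ5676. With the replicate number as a block, 5029 genes changed, 2438 higher and 2591 lower, and the call of ribosomal proteins ended (adjusted p = 0.0713).

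The risen share in the lowest expression class, 87.0%, was 90.2% with library totals, 89.5% with the GC and length correction and 92.6% with 10 classes, and 84.7% to 91.0% with 1 library left out. In the highest class, 30.3% became 37.8% with upper quartile scaling, 45.3% with library totals and 27.5% with the strict filter, and 26.1% to 33.9% with 1 library left out. The cause was not tested.

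Of 193 named genes, 174 kept their side of the threshold under every alternative that tested them, 18 lost their call under some alternative, and KRT19 gained one without EPZ5676 replicate 1 (adjusted p = 0.0359, with a range of 0.0359 to 0.613 over its 16 alternatives). Of the 18, 14 lost it without 1 of the libraries, KMT2A among them. At this depth the simulation recovered 40% of genes altered 1.2-fold, so unlisted small changes are not shown to be absent.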

Other observations

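Tests in this part chosen only after the results were seen were those on gene families, chromosomes, interferon ligands, immune cells, luminal keratins and the GC trend of the libraries, and the GC and length correction. Among 161 groups of genes that share a symbol root, keratins, the intermediate filaments of epithelia, stood out. Of 15 tested keratin genes, 11 rose and none fell, with a median log2 fold change of 0.43 (camera, adjusted p = 8.53e-05, and an adjusted p of 0.949 with an estimated correlation). KRT4 went from 5.49 to 33.5 CPM and KRT80 from 587 to 791 CPM. KRT81, at 1.28, and KRT86, at 0.99, are near-identical copies that can share reads. Under the GC and length correction the adjusted p was 9.31e-07. None of the 161 groups had an adjusted p under 0.949 with an estimated correlation. That setting gave the keratins the same value as many unrelated groups, so it cannot decide for or against a shift in any of them.

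Of 12 tested WNT ligand genes, 5 rose and none fell (adjusted p = 0.0434, and an adjusted p of 0.949 with an estimated correlation). WNT3A had a log2 fold change of 1.77 and WNT5A of 1.05. Of 12 PARP genes, 5 rose and 1 fell (adjusted p = 0.0434, an adjusted p of 0.949 with an estimated correlation, and an adjusted p of 0.0772 after the GC and length correction). Among them PARP10, PARP12, PARP14 and PARP9, which take part in antiviral responses, were at 2.71, 1.64, 2.27 and 2.02, and PARP1, a sensor of DNA breaks, was at −0.30. These genes were named after their values were seen.

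The 456 rises and 48 falls of at least 1 on the log2 scale were in a ratio of 9.50, and of 11.4 after the GC and length correction. Among genes with a mean of at least 5 CPM there were 130 such rises and 27 such falls. In 570 genes of families that are silent in most tissues, counts summed to 527 in EPZ5676 and 520 in DMSO, a ratio of 1.04 (exact 95% interval 0.923 to 1.18, counting error only). The fall of 272 of 958 genes on chromosome 19, where 61 rose, had an adjusted p of 8.18e-04 among 24 chromosomes, an adjusted p of 0.688 with an estimated correlation and of 0.954 after the correction. On chromosomes 22 and 16, 60 of 307 and 156 of 619 genes fell and 20 and 53 rose (adjusted p of 0.0262 for each, and also 0.688 and 0.954 in those 2 tests). The median log2 fold change of the fifth of genes with the longest span minus that of the fifth with the shortest was −0.0027. It was −0.08 after a separate correction of the fold changes for GC content and transcript length only, which left gene span in.

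The rise of the interferon list was weighed against 2 technical explanations. With 3 other scalings at least 34 of 36 members rose. That count could hardly have changed, because no scaling moved the median of all genes by more than 0.05 on the log2 scale. The list median of 2.12 is far larger than such shifts, and that size, not the count, argues against the scaling. Leukocytes among the cells would bring their own transcripts, but 8 leukocyte genes such as PTPRC and CD3E summed to at most 1.40 CPM in an EPZ5676 library and to 1.65 CPM in a DMSO library, while the interferon list went from at most 663 to at least 2345 CPM; a bound of 1 CPM set earlier was wrong because DMSO libraries already exceeded it. On the other side, the full list of 20 immune markers summed to 19.7 to 20.5 CPM in EPZ5676 and 12.4 to 14.8 CPM in DMSO, with LCP1 and ITGAM risen, but PTPRC, which all leukocytes express, had 3 reads in EPZ5676 and 1 in DMSO. A hypothesis is that the cells made interferon ligands, since 22 ligand genes had 32 reads in EPZ5676 (13, 11 and 8 per library) and 1 in DMSO, a ratio of 33.0 (exact 95% interval 5.51 to 1342, counting error only), with 14 on IFNL2, 10 on IFNL1, 4 on IFNL3 and 4 on IFNB1, and whether ligands came before the response or after it stays open.

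The fall of the estrogen-induced genes was weighed in the same way. After the GC and length correction 32 of the 48 members fell, so that trend does not account for the list. Fewer luminal cells would lower all luminal genes by about the list's median of −0.41, but KRT8, KRT18, KRT19, CDH1 and EPCAM were at 0.17, 0.32, −0.08, −0.25 and −0.19, a median of −0.081 that lies above −0.41 by more than the SD of the 5 values, 0.242. That SD measures the spread between the 5 genes and is no error bound on their median. On the other side, 11 of 24 genes of the luminal list fell and 5 rose. KRT8 and KRT18 were among the rises, but 11 of 15 tested keratin genes rose, so these 2 cannot mark the share of luminal cells. CDH1 and EPCAM fell by less than the −0.41 of the estrogen-induced list, and a smaller loss of luminal cells stays open. No biological explanation other than the treatment was tested.

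The third pattern was the relation of small changes to GC content. The correction ended 862 of the 4131 calls, or 20.9%, and 4 of these had an absolute log2 fold change of at least 1; in the 862 the median absolute log2 fold change went from 0.26 to 0.12 and the median SE from 0.08 to 0.06, so the calls ended because the changes shrank. The GC trend varied by 0.386 among the EPZ5676 libraries and by 0.193 among the DMSO libraries, against a difference of −0.25 between group means, which is consistent with a trend that differs between libraries whatever the treatment. EPZ5676 replicate 1, at −0.04, lay within the range of the DMSO libraries, −0.12 to 0.07. An effect of the treatment on GC-rich genes cannot be told apart from it, since the exact 2-sided permutation p between groups was 0.200 with 3 libraries per group, where the smallest possible is 0.100. The permutation took no account of the replicate number. The trend fell from replicate 1 to 3 in both groups, so part of the ranges may follow that number. Within each number the EPZ5676 library had the lower trend.

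Of the 10 ways to split the 6 libraries into groups of 3, only the real one, 1 of 10, gave as many as 4131 genes, and the highest of the others gave 0 (edgeR). With 10 splits no share under 0.05 can be reached. Every other split also puts libraries of both treatments in each group, so the treatment difference adds to the spread within groups. The 0 calls there are thus no measure of the calls that chance would give.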
